A study of Lichtheimia hyalospora and Lichtheimia corymbifera and Lichtheimia ramosa with 28 samples.

How the data were processed

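Total RNA from mycelia was poly-A selected, made into libraries with the Ion Total RNA-Seq Kit and sequenced on an Ion Proton, per the labels' protocols. The authors deposited 1 file of whole-number counts per library, with a gene ID and a count on each line and no header. The aligner, the counting tool, the strand setting and the genome builds are not given in the sources used here. The lowest value in each deposited count file was 1 and never 0. Either 1 was added to each count or 1 stood in place of 0, and the files do not tell which. A value of 1 was therefore read as no more than the floor. The sums over the least abundant genes of *L. hyalospora*, and the numbers of genes without a read, took 1 as no read instead. In *L. corymbifera* 479 of 12379 IDs, in *L. ramosa* 12 of 11510 and in *L. hyalospora* 90 of 12062 stood at 1 in all libraries of the species. How reads shared by near-identical genes were counted is not given in the sources used here, so values of gene families are uncertain.

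Groups came from the sample titles, which give the species, the treatment and a replicate number. Each group had 2 libraries, and nothing in the labels ties a replicate number to a culture or batch. Library totals were 10643879 to 31312327 counts. Replicate pairs were compared by a chi-square of their counts, which was 20.58 to 152.1 per gene, above the value of 1 that sampling noise gives, so no pair was taken as copies of 1 library and each library counted as 1 sample. Whether that spread arose between cultures or between preparations is not given in the sources used here. The labels give 1 collection number per species that stays the same and, in *L. corymbifera* and *L. hyalospora*, a second strain number that differs from library to library; 1 strain per species was assumed.

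Each species was fitted by itself with edgeR 4.0.16 (R 4.3.3), using trimmed-mean scaling, the default expression filter by group, robust dispersions and a quasi-likelihood F test, two-sided. All groups of a species shared 1 fit, since 2 libraries per group leave 4 residual degrees of freedom in *L. corymbifera* and *L. ramosa* and 6 in *L. hyalospora*. The filter left 10251, 11144 and 10940 genes in *L. corymbifera*, *L. ramosa* and *L. hyalospora*, and the common biological coefficient of variation was 17.3%, 19.8% and 16.1%. Genes were called at a Benjamini-Hochberg false discovery rate under 0.05 over the genes tested in a comparison. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of F. CPM values used the scaled library totals, and principal components used log2 CPM with a prior count of 2. The sums over the least abundant genes of *L. hyalospora* used library totals without scaling factors instead.

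The treatments were compared with the controls of their species, geldanamycin with DTT, and the 2 sets of controls of *L. hyalospora* with each other. The effect of heat plus NaCl minus that of heat was tested as a difference of differences. These tests, the rule for named IDs and most alternative settings were fixed before the data were examined. Comparisons of heat with DTT, of the NaCl controls with heat and of heat plus NaCl with other references were added afterwards. Overlaps of calls were set beside the number that independent lists would share, and correlations beside 20 simulations per species of unchanged groups against the same controls, in which libraries were drawn independently of their replicate number. Covariances were also taken with each of the 2 effects against a different control library.

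The files pair no gene ID with a name or product and no annotation was used, so no coordinates are given. The lists of chaperone, protein degradation, redox, ribosome, cell wall and other genes that were fixed in advance could not be matched and set tests were not run. By the rule for IDs without names, the text gives per species the 2 rising and 2 falling IDs with the largest absolute log2 fold change over its comparisons with control. They had to pass the test, reach a mean of 20 CPM in the higher group and have both treated libraries on one side of both controls. LRAMOSA01134 was added because a comparison had 1 call.

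Alternatives were relative log expression scaling, library totals only, DESeq2 1.42.0, no low-count filter, a filter of 5 CPM in 2 libraries, the libraries of the contrast only, the replicate number as a block, thinning to 10643879 counts per library, an absolute log2 fold change of at least 1 and leaving out each library in turn. With a library left out its group holds 1 library, which is assumed to vary like the other groups. Chosen after seeing the data were subtracting 1 from each count, leaving out the DTT libraries and exchanging the control sets of *L. hyalospora*.

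The fit was tested on simulated data with the control means and with the library totals and dispersions of the species' fit. In the geldanamycin group 200 genes were changed, and the other groups kept the control means. In *L. corymbifera* (9913 genes) 7.46%, 46.3% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 8 false calls among 104. In *L. ramosa* (11041 genes) the shares were 2.99%, 29.9% and 95.5%, with 11 false calls among 96, and in *L. hyalospora* (10785 genes) 7.46%, 47.8% and 83.3%, with 3 among 95. Counting intervals of ratios were exact binomial intervals at 95% on summed counts. Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. Figures were drawn with matplotlib 3.10.9.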

Results

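Poly-A RNA was sequenced from mycelia of 3 species of *Lichtheimia*, moulds of the order Mucorales that include agents of mucormycosis. The series compares their transcriptional responses to stress. Spores were grown in SUP medium, and each of the 14 groups held 2 libraries, 28 in all. Untreated controls grew for 22 h. Geldanamycin, an inhibitor of the chaperone HSP90, and dithiothreitol (DTT), a reducing agent that breaks disulfide bonds and disturbs protein folding in the endoplasmic reticulum, were each given for 2 h after 20 h of growth. Heat at 42 °C was given for 6 h after 16 h of growth. In *L. hyalospora* a further group received heat with 0.5 M NaCl on the same schedule, and it had its own untreated 22 h controls, called the NaCl controls here. The label of the heat plus NaCl group gives no temperature.

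Library totals ran from 10975236 to 17765771 counts in *L. corymbifera*, from 17505816 to 31312327 in *L. ramosa* and from 10643879 to 30477478 in *L. hyalospora*. Replicate libraries correlated across genes at 0.978 to 0.991 in log2 CPM (counts scaled by library total), and no pair agreed within sampling noise. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The files pair no gene ID with a name, so IDs are given as they stand and are few.

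**Figure D1:**
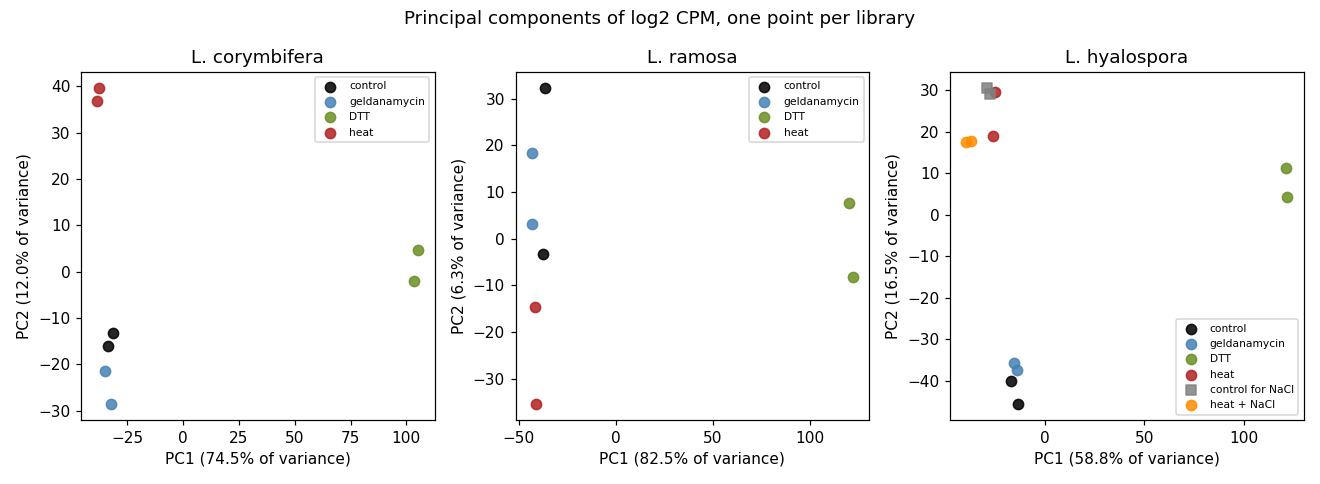
Principal components of log2 CPM, with 1 panel per species and 1 point per library; the axes are scores on the first and second components, with their percent of variance. The DTT libraries lie apart on the first component, which holds 74.5%, 82.5% and 58.8% of the variance in *L. corymbifera*, *L. ramosa* and *L. hyalospora*, and the NaCl controls of *L. hyalospora* lie beside the heat libraries.

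DTT changed most of the tested genes in all 3 species, both up and down. In *L. corymbifera* 3025 genes rose and 3172 fell, 60.5% of the 10251 tested. In *L. ramosa* 3101 rose and 3316 fell, 57.6% of 11144, and in *L. hyalospora* 3341 rose and 3486 fell, 62.4% of 10940. The median called gene changed 2.3-fold upward and 2.41-fold downward in *L. corymbifera*, 2.23-fold and 2.86-fold in *L. ramosa*, and 2.08-fold and 2.47-fold in *L. hyalospora*. Changes of at least 8-fold were reached by 289 rising and 148 falling genes in *L. corymbifera*, by 186 and 504 in *L. ramosa*, and by 219 and 428 in *L. hyalospora*.

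These genes held a large part of the transcriptome. The genes that rose under DTT took 14.8% ± 0.41 of all counts in the *L. corymbifera* controls and 46.8% ± 1.7 in the DTT libraries (SD, n = 2). The same quantity went from 18.5% ± 1.7 to 54.3% ± 1.7 in *L. ramosa* and from 20.2% ± 0.86 to 49.8% ± 2.8 in *L. hyalospora*. The genes that fell went from 48.4% ± 0.89 to 19.6% ± 0.69 in *L. corymbifera*, from 40.3% ± 2.8 to 11.2% ± 0.11 in *L. ramosa*, and from 38% ± 0.95 to 14.5% ± 0.028 in *L. hyalospora*. These sets were chosen by the test on the same libraries. With library totals in place of composition factors the median log2 fold change of all genes under DTT was −0.13 in *L. ramosa* and −0.15 in *L. hyalospora*, so changes are relative to that shift, and 2618 genes then rose and 3474 fell in *L. ramosa*, and 2781 and 3793 in *L. hyalospora*.

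**Figure D2:**
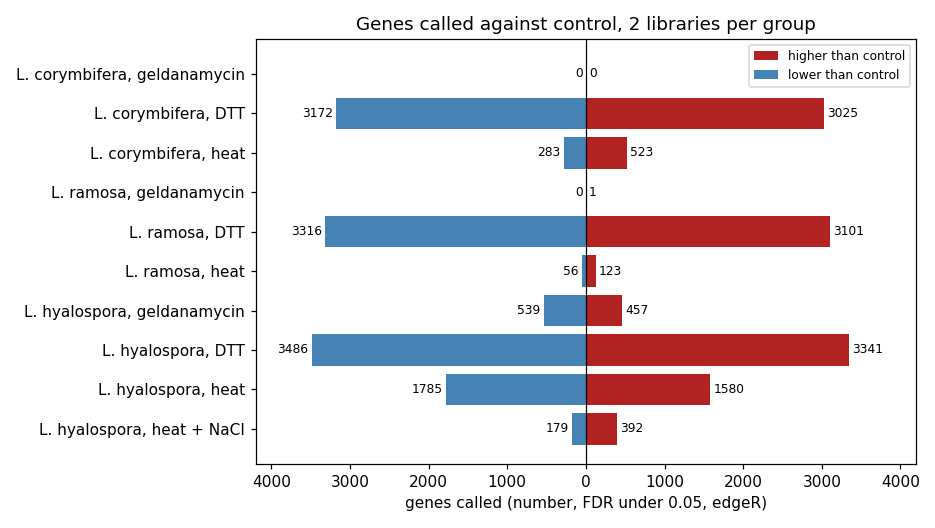
Genes called against control in each species and treatment (edgeR, false discovery rate under 0.05), as numbers of genes; red bars to the right count genes higher than control and blue bars to the left genes lower, with 2 libraries per group. DTT gave 6197, 6417 and 6827 calls in *L. corymbifera*, *L. ramosa* and *L. hyalospora*, and geldanamycin gave 0, 1 and 996. The fits left replicate numbers out.

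In *L. corymbifera* the ID with the largest rise under DTT was LCor00037.1, at 517 ± 38.8 CPM against 0.319 ± 0.215 in controls (SD, n = 2), a log2 fold change of 10.56 (SE 0.33), or 11.52 without control replicate 1. LCor05312.1 rose from 0.907 ± 0.811 to 702 ± 55.1 CPM, a log2 fold change of 9.51 (SE 0.438), and it also rose under heat, by 3.49 (SE 0.407). Without control replicate 1 these values were 10.99 and 4.97, and without control replicate 2 the value under heat was 2.88. LCor05141.1 fell from 218 ± 83.2 to 0.872 ± 0.102 CPM under DTT, a log2 fold change of −7.94 (SE 0.609). Under heat LCor05141.1 rose by 1.70 (SE 0.422) on the log2 scale, and that call was lost when any 1 of the 4 heat and control libraries was left out, with adjusted p of 0.0855 to 0.209 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. LCor06911.1 fell from 31.7 ± 9.54 to 0.385 ± 0.278 CPM under DTT, 83.1-fold, with a log2 fold change of −6.38, or −7.32 without DTT replicate 1 and −5.75 without DTT replicate 2.

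In *L. ramosa* LRAMOSA00932 rose under DTT from 1.63 ± 0.509 to 295 ± 5.58 CPM (SD, n = 2), a log2 fold change of 7.53 (SE 0.272). It fell under heat, with a log2 fold change of −2.76 (SE 0.351), a call that was lost without heat replicate 1 (adjusted p = 0.0767 by edgeR) or heat replicate 2 (adjusted p = 0.0561); over all alternatives its highest adjusted p was 0.0806. LRAMOSA01391 rose 143-fold under DTT, from 0.495 ± 0.0163 to 71.5 ± 1.75 CPM. LRAMOSA00169 was the most abundant ID of the geldanamycin libraries and stood at 8614 ± 1390 CPM in controls. Under DTT it fell to 11.5 ± 2.39 CPM, a log2 fold change of −9.54 (SE 0.4). LRAMOSA00024 fell from 563 ± 209 to 0.438 ± 0.137 CPM, a log2 fold change of −10.33 (SE 0.451).

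In *L. hyalospora* jgi.p|Lichy1|86926 rose under DTT from 0.494 ± 0.184 to 649 ± 50.6 CPM (SD, n = 2), a log2 fold change of 10.37 (SE 0.345). Against the NaCl controls, where the ID stood at 43.2 and 36.2 CPM, the log2 fold change under DTT was 4.03. For jgi.p|Lichy1|196160, with 1 and 3 counts in the controls and 878 and 522 under DTT, the ratio of summed counts was 442, with an exact 95% counting interval of 172 to 1630. Its log2 fold change was 8.67, or 9.56 with 1 subtracted from each count, 7.97 without control replicate 1 and 9.69 without control replicate 2. jgi.p|Lichy1|178150 fell 165-fold, from 50.9 ± 10.9 to 0.296 ± 0.0513 CPM, a log2 fold change of −7.36. Against the NaCl controls the log2 fold change was −6.47 for this ID, 7.09 for jgi.p|Lichy1|196160 and −6.935 for jgi.p|Lichy1|160051. jgi.p|Lichy1|160051 had a log2 fold change of −7.98 (SE 1.43) under DTT, but its controls stood at 174.9 and 11.04 CPM, and the value was −4.91 without control replicate 1, −8.89 without control replicate 2, −6.89 without DTT replicate 1 and −10.02 without DTT replicate 2. The counting interval covers counting error only.

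Heat changed fewer genes than DTT, and the numbers differed widely between the species. In *L. corymbifera* 523 genes rose and 283 fell, 7.86% of those tested, and 30 rising and 4 falling genes changed at least 8-fold. Heat in *L. ramosa* raised 123 genes and lowered 56, 1.61% of those tested. In *L. hyalospora* 1580 genes rose and 1785 fell, 30.8% of those tested, with 22 rising and 110 falling at least 8-fold. The genes that rose held 1.8% ± 0.078 of counts in controls and 4.6% ± 0.24 under heat in *L. corymbifera*, 0.536% ± 0.042 and 1.61% ± 0.21 in *L. ramosa*, and 8.26% ± 0.1 and 16.6% ± 0.24 in *L. hyalospora* (SD, n = 2). No correspondence of genes between species was used, so differences between species were not tested.

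The counts under heat moved with single libraries. Without control replicate 1, control replicate 2, heat replicate 1 or heat replicate 2, *L. corymbifera* had 263, 229, 335 and 443 calls. In *L. ramosa* 47 genes were called without control replicate 2, 51 without heat replicate 1 and 34 without heat replicate 2, while DESeq2 called 646. *L. hyalospora* had 2153 calls without control replicate 2 and 1859 without heat replicate 1. The share of calls that rose depended on the fit: it was 64.9% in *L. corymbifera* and 80.5% with library totals only, which put the median of all genes at 0.10 on the log2 scale; in *L. hyalospora* it was 47% and 58%, with a median of 0.10. In *L. ramosa* the share was 68.7% and by DESeq2 55.6%. With the replicate number as a block, heat gave 2592 calls in *L. corymbifera* (49% rising) and 1317 in *L. ramosa* (53.8% rising). With the NaCl controls in place of the other controls, heat gave 18 calls in *L. hyalospora*.

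Under geldanamycin 0 genes were called in *L. corymbifera* and 1 in *L. ramosa* by edgeR's quasi-likelihood test, in a fit that left replicate numbers out. At an unadjusted p under 0.05 there were 820 genes in *L. corymbifera*, where 512.6 were to come by chance, and 630 in *L. ramosa*, where 557.2 were. DESeq2 called 21 and 56, and a fit with the replicate number as a block called 330 and 79. Whether the numbers pair the libraries is open. The 95% interval of the effect lay within 2-fold either way for 73.2% of tested genes in *L. corymbifera* and 76.3% in *L. ramosa*. Counts were also simulated from the control means with the spread of the species' fit. Of genes changed 2-fold and 4-fold, 46.3% and 90.9% were recovered in *L. corymbifera*, and 29.9% and 95.5% in *L. ramosa*.

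The ID called in *L. ramosa*, named after its values were seen because it stood alone, was LRAMOSA01134. It rose from 13.2 ± 2.72 to 79.5 ± 5.59 CPM under geldanamycin (SD, n = 2), 6.01-fold, with an adjusted p of 0.0113 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It also rose under heat, with a log2 fold change of 2.10 (SE 0.198), and fell under DTT, with −3.55 (SE 0.238). The geldanamycin call was lost without any 1 of the 4 libraries compared and in 6 of 15 alternatives in all, where the log2 fold change ran from 2.40 to 2.82 and the highest adjusted p was 0.181.

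In *L. hyalospora* geldanamycin raised 457 genes and lowered 539, 9.1% of those tested. The rises were small, with a median of 1.65-fold and 80 genes of at least 2-fold. Of the falling genes 362 fell at least 2-fold and 71 at least 8-fold, and 68 of these 71 lay under 5 CPM in the controls. The rising genes held 3.19% ± 0.15 of counts in controls and 5.79% ± 0.49 under geldanamycin, and the falling genes 6.22% ± 0.037 and 2.95% ± 0.11 (SD, n = 2). jgi.p|Lichy1|178150, which fell under DTT, also fell under geldanamycin, with a log2 fold change of −1.04 (SE 0.191), a call lost without either geldanamycin library; against the NaCl controls the value was −0.15 (adjusted p = 0.625 by edgeR). The number of calls was 544 without control replicate 1, 203 without geldanamycin replicate 1, 97 without geldanamycin replicate 2 and 2589 against the NaCl controls, and the share that rose was 45.9%, or 27.9% with library totals only and 55.4% by DESeq2.

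Geldanamycin and DTT were matched in time, and the direct comparison separated them. Between the treatments 6376 genes differed in *L. corymbifera*, 6798 in *L. ramosa* and 6567 in *L. hyalospora*, of which 3286, 3528 and 3351 were higher under geldanamycin. The most extreme IDs under DTT were among them, such as LCor00037.1 at 0.498 and 0.228 CPM under geldanamycin and 490 and 545 CPM under DTT. The doses are not given in the sources used here.

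The lists of DTT and heat calls were set beside the overlap of independent lists. In *L. corymbifera* 134 genes rose under both, where independent lists would share 154, and 125 fell under both, where they would share 87.6. A further 208 genes fell under DTT and rose under heat, where independence gives 162. In *L. ramosa* 41 rose under both (34.2 by independence) and 36 fell under both (16.7). In *L. hyalospora* 600 rose under both (483) and 899 fell under both (569). Across genes the correlation of the 2 effects was 0.076, 0.0616 and 0.249 in *L. corymbifera*, *L. ramosa* and *L. hyalospora*, and genes are not independent replicates.

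The stresses of a species share their control libraries, which alone gives a correlation. Simulated unchanged groups against the same controls gave a covariance of 0.0659 for DTT and heat in *L. corymbifera*, where 0.0673 was observed. The simulated and observed covariances were 0.0536 and 0.046 in *L. ramosa*, and 0.0448 and 0.311 in *L. hyalospora*. The simulated correlations were 0.5, 0.505 and 0.494. They hold for groups without effects and are no baseline for correlations of real effects, so only the covariances compare. Same-numbered libraries deviated together in the data but not in the simulations, so the simulated covariances may be too large. Whether shared controls account for the observed covariance is therefore open in *L. corymbifera* and *L. ramosa*. The number of genes called in one direction under both was 259 in *L. corymbifera*, and 91, 75, 113 and 152 without control replicate 1, control replicate 2, heat replicate 1 and heat replicate 2. In *L. ramosa* it was 77, and between 15 and 30 without any of control replicate 2, the DTT libraries or the heat libraries, 1 at a time. In *L. hyalospora* it was 1499, and 981 without control replicate 2 and 884 without heat replicate 1.

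Set against the same controls, geldanamycin and heat moved many of the same genes in *L. hyalospora*. Of the 457 genes that rose under geldanamycin 271 also rose under heat, where independent lists would share 66, and of the 539 that fell 341 also fell, against 87.9. Only 7 and 19 genes went in opposite directions. The covariance of the 2 effects was 0.285, where the simulation gave 0.0449, and the correlation was 0.537 against a simulated 0.484. With DTT, geldanamycin shared 191 rising genes (140 by independence) and 356 falling genes (172), with a covariance of 0.218 against a simulated 0.0448 and a correlation of 0.233 against 0.468. The 612 genes shared with heat became 364 without control replicate 2, 147 without geldanamycin replicate 1 and 70 without geldanamycin replicate 2; the 547 shared with DTT became 275 without control replicate 1, 117 without geldanamycin replicate 1 and 60 without geldanamycin replicate 2. For geldanamycin and heat the covariance was 0.0306 in *L. corymbifera*, against a simulated 0.0674, and 0.0688 in *L. ramosa*, against 0.0542, with correlations of 0.131 and 0.425 against 0.502 and 0.512. For geldanamycin and DTT it was 0.0431 against 0.0672, and −0.0165 against 0.0538, with correlations of 0.0789 and −0.0321 against 0.51 and 0.505. Here too the simulated correlations hold for groups without effects and are no baseline for the observed ones. With the 2 effects taken against 1 control library each, so that no library was shared, the mean covariance over both ways round was 0.223 for geldanamycin and heat, 0.152 for geldanamycin and DTT and 0.248 for DTT and heat in *L. hyalospora*. In the same order it was −0.0207, −0.00659 and 0.0197 in *L. corymbifera* and −0.00355, −0.0973 and −0.0358 in *L. ramosa*. A deviation that same-numbered libraries share enters such a pair of effects with opposite signs. These covariances may therefore be too small. The lists of calls used the same controls, so part of an excess over independent lists may come from these. In *L. hyalospora* both single control libraries came from the set that differed from the NaCl controls at 3349 genes. An offset of that whole set would remain in the covariances without a shared library. Against the NaCl controls heat gave 18 calls and geldanamycin 2589.

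Heat with NaCl, set against its own controls, changed 571 genes of *L. hyalospora*, 392 upward and 179 downward, 5.22% of those tested. Of the rising genes 45 rose at least 8-fold. The rising genes held 1.72% ± 0.15 of counts in the NaCl controls and 4.28% ± 0.0085 under heat with NaCl, and the falling genes 2.69% ± 0.22 and 1.23% ± 0.071 (SD, n = 2). Against all 3 references, the NaCl controls, the heat libraries and the other controls, 139 of the 392 genes were called higher and 53 of the 179 lower, while 58 and 21 were called the other way against the heat libraries or the other controls. The calls numbered 239, 235, 232 and 244 without NaCl control replicate 1, NaCl control replicate 2, heat plus NaCl replicate 1 and heat plus NaCl replicate 2. With the heat libraries as the reference there were 900 calls, and with the other controls 2565.

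The NaCl controls differed from the other controls and resembled the heat libraries. Between the 2 sets of controls, both untreated for 22 h per the labels, 1679 genes were higher and 1670 lower in the NaCl controls, 30.6% of those tested. Between the NaCl controls and the heat libraries 18 genes differed by edgeR's test. Across libraries the correlation of log2 CPM was 0.979 to 0.986 between NaCl controls and heat, and 0.944 to 0.95 between NaCl controls and the other controls. jgi.p|Lichy1|86926 stood at 0.364 and 0.623 CPM in the other controls, at 33.2 and 26.4 CPM under heat, at 43.2 and 36.2 CPM in the NaCl controls and at 0.651 and 1.11 CPM under heat with NaCl. Its log2 fold change was 5.93 (SE 0.317) under heat and −5.43 (SE 0.308) under heat with NaCl, each against its own controls; against the other controls the latter was 0.91 and did not pass. The share of the differing genes that was higher in the NaCl controls was 50.1%, or 62.5% with library totals only, which put the median of all genes at 0.11 on the log2 scale, and without NaCl control replicate 2 there were 2061 calls.

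Heat alone and heat with NaCl, each against its own controls, gave opposite effects on many genes. The test of the difference called 2848 genes, 1580 higher and 1268 lower with NaCl. Of the genes that fell under heat alone 205 rose under heat with NaCl, where independent lists would share 64, and of those that rose 103 fell, against 25.9. In one direction 35 genes rose in both (56.6 by independence) and 11 fell in both (29.2). The correlation of the effects across genes was −0.345 and the covariance −0.174, with no library in common. The NaCl controls lay near the heat libraries, however, with 18 genes differing. Heat plus NaCl minus NaCl controls was therefore close to heat plus NaCl minus heat. Set against heat minus control, such a contrast can give opposite effects through its reference alone. The 46 genes shared in one direction became 19 without NaCl control replicate 1, 23 without NaCl control replicate 2, 21 without heat plus NaCl replicate 1 and 26 without heat plus NaCl replicate 2. The share of the 2848 genes that was higher with NaCl was 55.5%, or 45.1% with library totals only, where the median was −0.12 on the log2 scale.

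**Figure D3:**
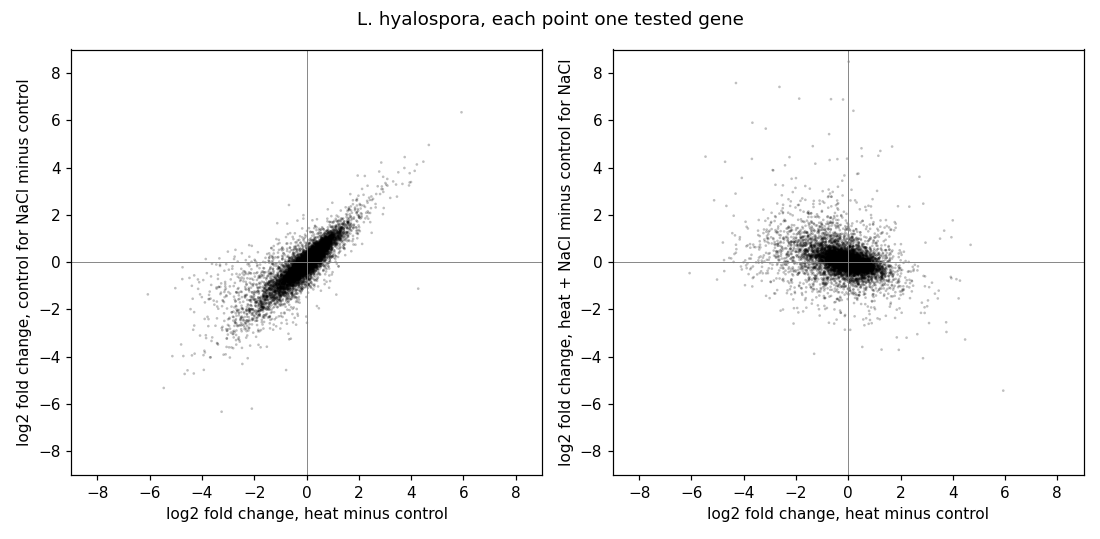
Log2 fold changes of the 10940 tested genes of *L. hyalospora*, 1 point per gene; the x axis is heat minus control, and the y axis is NaCl control minus control on the left and heat plus NaCl minus NaCl control on the right. The correlation is 0.846 on the left, where both axes share the control libraries (simulated unchanged groups gave 0.477), and −0.345 on the right, where no library is shared. The simulated value holds for groups without effects and is no baseline for the observed one. On the right, the NaCl controls used as the reference resembled the heat libraries of the x axis.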

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

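The tests on the NaCl controls below were chosen after the result was seen, while the difference of effects and the comparison of the 2 sets of controls were planned. In *L. hyalospora* the effect of heat plus NaCl, against its own controls, differed from the effect of heat for 2848 genes by the test of the difference. That contrast takes in both sets of controls, and 3349 genes differed between these.

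The NaCl controls lay near the heat libraries: 18 genes differed between them, where 3349 differed between the 2 sets of controls. Depth does not account for it, since 3181 genes still differed between the control sets with every library thinned to the smallest, and neither do shared control libraries, since the covariance of the 2 effects exceeded the simulated one by 0.532. Heat exposure of the NaCl controls, or another culture condition they shared with the heat libraries, is a candidate explanation. Heat minus geldanamycin, which shares no library with NaCl control minus control, correlated with it at 0.623 across genes, and 2175 of its 2435 called genes moved the same way. That restates the resemblance without shared libraries, and a shared batch could give it too. A library batch that sets the level of low-abundance genes was looked for in sums over these genes, with a value of 1 taken as no read. The 1198 least abundant genes, scaled by library total only, summed to at most 96.79 CPM in the heat libraries. That lay below the 122.3 to 172.2 CPM of the NaCl sets, and the DTT libraries, at 102.6 and 111.7 CPM, lay between. A treatment may change these sums within 1 batch, so they cannot exclude such a batch. A batch of any kind cannot be told apart, because the labels name none. If heat exposure or another shared culture condition holds, heat plus NaCl against its own controls may show mostly the effect of NaCl. An effect of NaCl that opposes heat stays open as a biological explanation.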

How the results depend on the processing

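The subtraction of 1 from each count, the fits without DTT libraries and the exchanged controls were chosen after the data were seen. Outside single-library omissions, 148 counts of calls stayed within 1.5 times and 32 did not; with 1 library omitted, 60 did and 42 did not. For named IDs 248 and 83 values kept direction and call, 8 and 13 lost the call, and 2 changed sign: jgi.p|Lichy1|86926 had a log2 fold change of −0.41 under heat against the NaCl controls, and 0.91 under heat with NaCl against the other controls. The cause was not tested unless stated. Gene list alternatives were not run, for want of names. Values near the floor of 1 limit the folds of low genes.

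With the replicate block, *L. corymbifera* had 330 geldanamycin calls, 2592 heat calls, 49% of them rising, and 1006 shared by DTT and heat in one direction, and *L. ramosa* had 79, 1317, 53.8% of them rising, and 536; other counts stayed within 1.5 times. Same-numbered libraries deviated together at 0.326 to 0.487 in *L. corymbifera*, 0.322 to 0.52 in *L. ramosa* and 0.104 to 0.383 among the control, geldanamycin, DTT and heat groups of *L. hyalospora*, and down to −0.26 with its NaCl controls; with 2 numbers and no batch in the labels it is open whether the numbers pair them. An absolute log2 fold change of at least 1, which by construction takes fewer genes, left 3960 DTT, 482 heat and 4235 geldanamycin minus DTT calls in *L. corymbifera*. In *L. hyalospora* it left 442 geldanamycin, 4011 DTT, 1403 heat, 3864 geldanamycin minus DTT, 377 heat plus NaCl and 1385 control-set calls. DESeq2 called 21 genes under geldanamycin in *L. corymbifera*, and in *L. ramosa* 56 under geldanamycin and 646 under heat. Fitting the contrast's libraries only, with fewer samples, gave 493 heat calls in *L. corymbifera*, 0 geldanamycin and 12 heat calls in *L. ramosa*, and 417 geldanamycin, 1991 heat and 981 heat plus NaCl calls in *L. hyalospora*. Library totals only gave 44 calls shared by DTT and heat in *L. ramosa* and 639 geldanamycin calls in *L. hyalospora*. Without the DTT libraries *L. ramosa* had 0 geldanamycin and 91 heat calls. Against the NaCl controls *L. hyalospora* had 2589 geldanamycin and 18 heat calls. Heat plus NaCl gave 900 calls against the heat libraries and 2565 against the other controls.

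With 1 library omitted, heat calls ran from 229 to 443 in *L. corymbifera*, from 34 to 239 in *L. ramosa* and from 1859 to 2953 in *L. hyalospora*. Geldanamycin calls were 0 throughout in *L. ramosa* and ran from 97 to 679 in *L. hyalospora*. Heat plus NaCl calls ran from 232 to 244 and control-set calls from 2061 to 2693. Calls shared by DTT and heat ran from 75 to 181, from 15 to 110 and from 884 to 1437 in *L. corymbifera*, *L. ramosa* and *L. hyalospora*. In *L. hyalospora* geldanamycin shared 60 to 567 with DTT and 70 to 477 with heat, and heat shared 19 to 51 with heat plus NaCl.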

Other observations

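The direct comparison of heat with DTT and the tests on low-abundance genes and on consecutive IDs were chosen after the results were seen. Some genes that heat raised went the other way under DTT. In *L. corymbifera* 208 of the 523 genes that rose under heat fell under DTT (162 by independence). Of the 523, 394 were called higher under heat than under DTT and 61 lower. In *L. ramosa* 37 of 123 fell under DTT (36.6), while 93 of the 123 were called higher under heat and 9 lower. In *L. hyalospora* 479 of 1580 fell under DTT (503), while 928 of the 1580 were called higher under heat and 277 lower. Choosing genes by their rise under heat favours the first direction. Of the genes that fell under heat, 81 of 283, 7 of 56 and 410 of 1785 rose under DTT in *L. corymbifera*, *L. ramosa* and *L. hyalospora*, where independence gives 83.5, 15.6 and 545.

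Genes of low abundance stood higher in both control sets and in heat plus NaCl of *L. hyalospora* than in the geldanamycin, DTT and heat libraries. The 1198 least abundant IDs summed to 249.1 and 190 CPM in the controls and to 55.23 and 54.58 CPM under geldanamycin. These sums, and the genes without a read below, took a value of 1 as no read. With 1 kept, the 1198 IDs would exceed the geldanamycin sums through the floor alone. Whether that reading is right is open, and sums of the values as deposited are not given. At one depth at most 792 genes lacked a read in the 6 libraries of both control sets and heat plus NaCl. At least 880 did in each of the others. Depth thus does not account for the higher level. The log2 of the summed CPM lay 0.943 higher under heat plus NaCl than under heat (95% interval 0.516 to 1.37, t test on 6 residual degrees of freedom). The pattern that sets these groups apart was seen in the same libraries. That interval therefore cannot decide on a drop that heat brings with or without NaCl. A drop that NaCl prevents was not tested. Of the falls of at least 8-fold under geldanamycin 68 of 71 lay under 5 CPM in the controls, and of all falling calls 194 of 539 did. The 1198 IDs had a mean of at most 0.301 CPM over all libraries, far below that limit. The split at 5 CPM therefore cannot tell whether the pattern is a source of either set of falls.

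Genes with consecutive IDs changed together. Under DTT the log2 fold changes of neighbouring IDs correlated at 0.145 in *L. corymbifera*, 0.147 in *L. ramosa* and 0.16 in *L. hyalospora*. The order was that of ID numbers, or of listing in *L. hyalospora*, and the highest of 1000 shuffles was 0.0365. Between IDs 2 places apart the correlation was 0.0277, 0.0296 and 0.0421. Fold changes were thus not spread at random along the IDs, which alone does not tie the order to a response. Under geldanamycin neighbouring IDs correlated at 0.086 in *L. corymbifera* and 0.0767 in *L. ramosa*, where 0 and 1 genes were called. In all 9 tests, over geldanamycin, DTT and heat, the permutation p and its Benjamini-Hochberg adjusted value were 0.001, the smallest that 1000 shuffles can give. If ID order follows position in the genome, neighbouring genes may respond alike, or reads may be shared between overlapping or duplicated neighbours; positions were not used here, and neither was tested.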
